A study of Arabidopsis thaliana with 8 samples.

How the data were processed

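Total RNA of wild-type Arabidopsis thaliana plants of the Landsberg ecotype was hybridised to 8 single-channel arrays, 4 for each of the red-light levels of 20 and 200 µE, both given for 48 hours. Groups and replicate numbers 1 to 4 were taken from the labels. The tissue, the plants' age and the array's make are not given in the sources used here, and the labels give the light level as µE with no area or time unit. Nothing in the labels says that the replicates came from separate plants, so p-values measure only the spread between these arrays, which may be technical.

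The deposited values are intensities, 1 per probe and array, for 3439 probes. How the authors made them is not given in the sources used here. Read from the values alone, they are on a linear scale, hold no negative number, and were set to 0 on 476 to 604 probes per array. From 1 to 4 probes per array share a maximum that rounds to 100.0 on every array, so each array appears to have been scaled to its brightest probes. Of the probes, 5 sat at that maximum on at least 1 array, and their differences have only a bound. Medians of the positive values differed by more than 10% between arrays, and by the rule fixed beforehand the arrays were therefore quantile normalized. This makes the distribution of values identical on all arrays, so a change in the bulk of the probes cannot be seen. Every direction given is relative to the other probes of the array. The plan fixed beforehand took the array to be selected for nuclear genes of plastid proteins. If so, a shift shared by plastid genes may be hidden, also in tests of a list against the other probes. The number of arrays limits the precision, and no depth or detection call was used here.

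Values at 0 were set to the lowest positive value of their array, the arrays were quantile normalized, and log2 was taken. The rule fixed beforehand did not say whether the floor is set before or after normalization. Both orders were run, and the choice was made after both counts of changed probes had been seen. With a floor set per array after normalization, the 320 probes at 0 on all 8 arrays received a difference between the light levels that comes from the floor alone, so the floor was set first, which gives those probes a difference of 0. A single common floor for all arrays set after normalization was then run as a check. Log2 values were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 4 arrays against 4, no covariate), two-sided, with Benjamini-Hochberg adjustment over all 3439 probes and a threshold of 0.05. Differences are the mean at 200 µE minus the mean at 20 µE. No probe was left out of this fit. The 320 probes at 0 on all arrays have no spread, and they entered the variance estimate that eBayes shares between probes. A fold is given only for probes above 0 in both groups.

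Same-numbered arrays of the 2 light levels were checked for a shared deviation from their group means over the 2600 probes above 0 on all arrays. The correlation of the deviations ran from 0.707 to 0.735 in the 4 same-numbered pairs, against 0.444 to 0.462 for the 4 pairs of a different number within replicates 1 and 2 or within replicates 3 and 4, and −0.623 to −0.556 for the 8 pairs across these sets. The numbers were therefore taken as pairing the arrays, from the data and not from the labels, and values with the replicate number as a block are given where they change a call. No 2 arrays held identical values. The sets of replicates 1 and 2 and of replicates 3 and 4 were seen in the data and are not groups of the study.

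Genes were named from the platform's annotation, which lists 1562 of the probes, 692 with 1 gene and 870 with several. Of the 692, 690 matched the reference gene table of assembly TAIR10.1, which was used for names only, and 2 did not. They name 689 loci. The other 1877 probes are unnamed here, and no gene was named from a probe with several. No coordinate is given because the values name no genome build. Before the data were examined, 25 gene lists with 401 genes were fixed, of which 22 genes lay on single-gene probes. Only the list of plastid ribosomal proteins reached the minimum of 5 measured members. The lists fixed as markers of non-green plastids and of senescence had 0 measured members, so neither could be read. From the annotation, 5 further lists were written before any difference between the light levels was computed: photosynthetic apparatus, organelle gene expression, cell division, developmental regulators, and redox and defence.

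Lists were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation beside it, and with fry as a description. An exact permutation test of the mean of the members used all 70 assignments of the arrays, with a smallest two-sided p of 0.0286. It takes the 8 arrays as exchangeable, which their sets and pairing do not allow. With the pairing kept, fewer assignments exist and the smallest possible p is larger. The named genes followed a rule fixed beforehand: the 10 largest changes in each direction among genes past the threshold whose groups did not overlap, the 2 members of smallest p in each tested list, and 10 light-response genes whatever their values, of which 0 lay on a single-gene probe. The rule was applied to single-gene probes above 0 in both groups, and its second part was extended to the added lists.

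On simulated data with the measured spread and set structure, for this comparison of 4 against 4 arrays and all 3439 probes, the fit recovered 8.96% of changes of 0.5 on the log2 scale, 32.8% of changes of 1 and 71.2% of changes of 2, with 1 false call among the 2600 probes above 0 on all arrays. Probes at 0 were left out of that false-call count because the simulation kept the measured zeros in place. With the replicate block the recovered shares were 22.4%, 56.7% and 81.8% with 6 false calls. With the array set as a block they were 43.3%, 73.1% and 93.9% with 28 false calls. The simulation held no shared deviation of same-numbered arrays and no light effect that differs between the sets. Its figures therefore do not show how the fits behave on arrays with that structure.

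Alternatives fixed beforehand were the deposited values with no further normalization, median centring, cyclic loess, a filter on the lowest 25% of probes, a filter on probes at 0 on any array, a pseudocount at the 10th percentile of the positive values (0.0932), the replicate block, eBayes with trend and robust settings, a plain unequal-variance test, an estimated correlation in camera, and leaving out each array in turn. Quantile normalization was also listed as an alternative and became the main setting. Added after the data had been seen were the 2 other placements of the floor, the array set as a block, each array set alone, and the arrays of each set averaged.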

Results

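Transcript levels were measured in wild-type Landsberg plants kept for 48 hours under red light at 20 or 200 µE, on 4 arrays each. The comparison asks which transcripts differ between dim and bright red light. As deposited, the median intensity of the probes above 0 was 0.305 ± 0.044 (SD, n = 4) at 20 µE and 0.543 ± 0.034 (SD, n = 4) at 200 µE. The exact permutation p of 0.0286 is the smallest that 4 against 4 arrays can give when their pairing and sets are ignored. The summed intensity differed less, 2897 ± 336 (SD, n = 4) against 3493 ± 136 (SD, n = 4). Values of 0 were listed on 591.5 ± 13.9 (SD, n = 4) probes per array at 20 µE and on 511 ± 33.1 (SD, n = 4) at 200 µE. Over the 2600 probes above 0 on all arrays, the median log2 difference in the deposited values was 1.02 in the dimmest of 4 equal classes of brightness, 0.91 and 0.83 in the middle classes and 0.47 in the brightest. All differences below are relative to the bulk of the array, after quantile normalization. Without it the median log2 difference of all probes was 0.99. That median includes the 320 probes at 0 on all arrays, whose difference of 4.53 there comes from the floor alone.

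**Figure D1:**
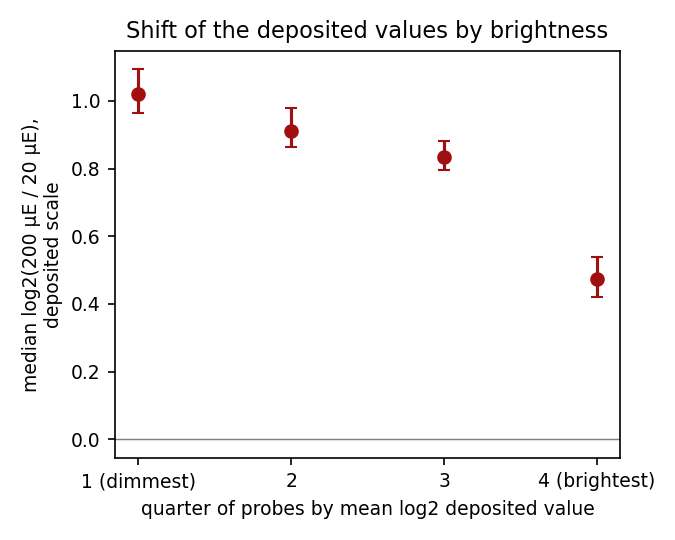
Median log2 ratio of the deposited intensities at 200 µE over 20 µE (vertical axis, log2 units) in 4 classes of 650 probes each, ordered by mean log2 deposited value (horizontal axis). Bars are 95% bootstrap intervals over probes, which are not independent replicates; the median falls from 1.02 in the dimmest class to 0.47 in the brightest.

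Bright red light went with a higher signal for the chloroplast peroxiredoxin gene AT3G52960 and a lower signal for CCS, which encodes the copper chaperone of superoxide dismutase. AT3G52960 rose from a normalized intensity of 0.182 ± 0.0246 (SD, n = 4) to 0.372 ± 0.0603 (SD, n = 4), a log2 difference of 1.03 ± 0.15 (SE; limma, adjusted p = 0.0111). CCS fell from 0.456 ± 0.0908 (SD, n = 4) to 0.232 ± 0.0278 (SD, n = 4), with a log2 difference of −0.96 ± 0.15 (SE; limma, adjusted p = 0.016). In the deposited values AT3G52960 was also higher, by 2.08 on the log2 scale, while CCS was level at −0.01, so the fall of CCS is a fall against the other probes. FZL, a dynamin-related GTPase of chloroplast membranes, fell by 0.80 ± 0.13 (SE; limma, adjusted p = 0.0187), though its deposited values were higher at 200 µE by 0.54 and its adjusted p was 0.0513 with the replicate block. The call of FZL also ended with median centring (−0.30; limma, adjusted p = 0.363) and cyclic loess (−0.58; limma, adjusted p = 0.122).

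Among the other genes that rose, AT4G27250 went from 1.74 ± 0.219 (SD, n = 4) to 3.28 ± 0.14 (SD, n = 4), a 1.90-fold change (limma, adjusted p = 0.00321). AT1G01080 rose 1.37-fold with an adjusted p of 0.00367 by limma. The remaining genes among the 10 largest rises were AT1G07460, AT4G39690, AT4G18540, AT3G54930, AT4G19900, AT1G68660 and AT2G46850, with log2 differences from 1.39 (AT1G07460) to 0.26 (AT2G46850). AT1G68660, which encodes a plastid ClpS protease adaptor, rose by 0.34 ± 0.05 on the log2 scale (SE; limma, adjusted p = 0.0154). With median centring in place of quantile normalization only AT3G52960 of the 10 rises kept its call. AT4G39690 was then at −0.06 (limma, adjusted p = 0.833), and AT4G19900 passed in the opposite direction, at −0.75 (limma, adjusted p = 0.0362). Median centring subtracts 1 amount per array from all its probes, so it keeps the smaller rise of the brightest class in the deposited values. Bright probes such as AT4G39690 and AT4G19900, at percentiles 97.2 and 98.7 of brightness, therefore stay lower against dim ones. Quantile normalization makes the distributions identical and so evens out that difference between the classes. Which of these settings is nearer the RNA levels was not tested. Leaving out the lowest 25% of probes or those at 0 on any array ended 6 of the 10, AT4G18540, AT3G54930, AT4G19900, AT1G01080, AT1G68660 and AT2G46850. Both filters were applied after normalization, so the log2 differences of these genes did not change. What changed was the variance estimate shared between probes, which in the main fit includes probes with no spread, and the number of probes adjusted for. With the deposited values 9 of the 10 rises kept their call. There 883 of 927 calls were higher, so a kept rise says little. AT2G46850 kept its call at 0.98, near the median of 0.99 over all probes. AT4G19900 was the rise that lost its call there, at 0.10 (limma, adjusted p = 0.575). Cyclic loess ended the call of AT4G19900 as well, at 0.24 (limma, adjusted p = 0.255). Among the normalizations run, its rise passed only with quantile normalization. The replicate block ended the calls of AT1G07460 (limma, adjusted p = 0.0663, from 0.0498) and AT4G18540 (0.0809, from 0.0472).

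The largest fall was that of AT1G24040, from 0.503 ± 0.0419 (SD, n = 4) to 0.22 ± 0.031 (SD, n = 4), a log2 difference of −1.20 ± 0.11 (SE; limma, adjusted p = 0.00187). AT5G26850 fell by 1.16 ± 0.10 (SE; limma, adjusted p = 0.00154) and AT1G63720 by 1.02 ± 0.10 (SE; limma, adjusted p = 0.00197). AT3G26630 went from 15.5 ± 4.1 (SD, n = 4) to 7.34 ± 0.662 (SD, n = 4), and its deposited values were lower too, by −1.26 on the log2 scale. AT5G52530, AT3G27110, AT1G13990 and AT1G34270 fell too, with log2 differences of −1.16, −1.05, −1.04 and −0.90. Of the 10 falls it was AT3G26630 alone that kept its call in the deposited values, where most probes rose. There AT1G24040, AT5G26850, AT5G52530, AT3G27110, AT1G13990 and AT1G63720 differed by −0.25, −0.69, −0.19, −0.02, −0.61 and −0.08, and AT1G34270 by 0.02. Median centring kept 8 of the 10, and the replicate block ended the call of AT1G13990 (limma, adjusted p = 0.0639).

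**Figure D2:**
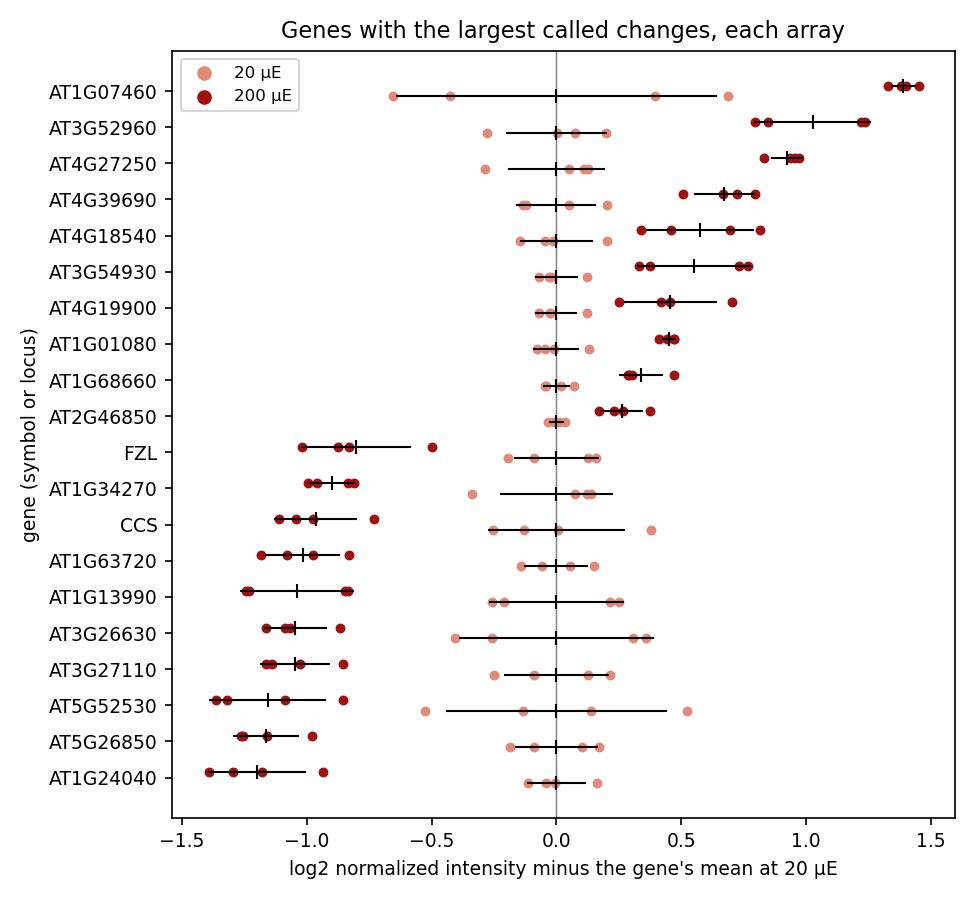
Log2 normalized intensity of each array minus the gene's mean at 20 µE (horizontal axis) for the 10 largest rises and 10 largest falls among single-gene probes past the threshold. Each dot is 1 array, with the mean (tick) and SD (bar) of 4 arrays; the largest mean difference upward is 1.39 (AT1G07460) and downward −1.20 (AT1G24040), and with median centring AT4G39690 and AT4G19900, or without normalization AT1G34270 and FZL, turn direction.

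Of the 3439 probes, 235 passed the threshold, 79 higher and 156 lower at 200 µE. Among the 690 single-gene probes, 37 passed, 12 higher and 25 lower. The groups overlapped in none of the 235, and 484 probes (15.5% of those above 0 on some array) had groups that did not overlap, against 2.86% if all arrays were exchangeable, which their sets and pairing do not allow. The 7 other splits that part all 4 replicate numbers gave 0.0321% to 0.834%, and replicates 1 and 2 against 3 and 4 gave 39.1%. Those 7 splits mix the light levels within each side, so the light difference itself can lower their share. The median absolute log2 difference was 0.84 among called probes above 0 in both groups. Of these, 19 were at least 2-fold higher and 62 at least 2-fold lower. In the simulated data small changes were recovered less often, so the sizes of called probes do not describe all changes. The replicate block raised the count to 619 (272 higher, 347 lower), of which 202 were among the 235. The balance of directions depended on the scaling. The deposited values gave 883 higher and 44 lower. Median centring, which left a median difference of 0.14 over all probes, those at 0 included, gave 42 higher and 170 lower. Of the 235 calls, 215 lay on probes above 0 on all arrays, yet leaving out probes at 0 on any array gave 156. A floor set per array after normalization gave 97 calls, the arrays of each set averaged 6, and leaving out single arrays 140 (20 µE replicates 3 or 4) to 174.

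AT4G02580, which encodes a subunit of mitochondrial complex I, was listed at 0 on all 4 arrays at 20 µE and at a deposited intensity of 0.174 ± 0.122 (SD, n = 4) at 200 µE. It was 1 of 15 probes at 0 on every array at 20 µE and above 0 on every array at 200 µE, and it was the only single-gene probe among them. The opposite pattern was seen on 1 probe. These probes are among the 235, but the 0s stand at an assigned floor with almost no spread, so their p-values are not given and add nothing to the pattern of 0s.

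The redox and defence list held 1 member that rose, AT3G52960, and 1 that fell, CCS, of 7 measured. NTRC, a chloroplast thioredoxin reductase, had a log2 difference of 0.58 ± 0.15 (SE; limma, adjusted p = 0.0775, and 0.0177 with the replicate block), and GLDH one of 0.02 ± 0.07 (SE). SRX and GLX2-1 were at 0 on 1 and 2 arrays at 20 µE. Adjusted over the list alone, 2 members were higher and 1 lower. Over the list, 3 members had an unadjusted p under 0.05. The median log2 difference was 0.92, or 0.58 without members at 0 on any array, and camera gave an adjusted p of 0.367. The adjusted p was 0.614 with an estimated correlation.

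None of the 13 measured members of the photosynthetic apparatus list passed the limma threshold over all probes, 3 had an unadjusted p under 0.05, and adjusted over the list alone 2 were lower. LHB1B2, a light-harvesting chlorophyll-binding protein of photosystem II, had 15.8 ± 6.11 (SD, n = 4) at 20 µE and 6.81 ± 1.01 (SD, n = 4) at 200 µE (limma, adjusted p = 0.0809, and 0.0482 with the replicate block). Its gene has close relatives whose transcripts the probe could not be shown to exclude. AT1G74470, the geranylgeranyl reductase of chlorophyll synthesis, had 4.09 ± 0.46 (SD, n = 4) and 2.78 ± 0.408 (SD, n = 4). Its adjusted p was 0.0615 by limma, and 0.0458 with the sets of replicates 1 and 2 and of 3 and 4 as a block. The fit with that block gave 28 false calls in simulated data, which left out the pairing of the arrays. LHB1B2 and AT1G74470 were both lower in the deposited values as well, by −1.34 (limma, adjusted p = 0.0317) and −0.47 (0.13). With median centring they were at −2.18 (limma, adjusted p = 0.00759) and −1.31 (0.0115), so that both passed there. Median centring keeps the smaller rise of bright probes in the deposited values, which quantile normalization evens out. These genes lay at percentiles 98.8 and 97.1 of brightness, so that smaller rise enters their passes there. The passes are therefore not independent support for a fall of these genes in particular. PSAN, PSBY and PRK had log2 differences of −0.15, 0.35 and −0.05. SBPASE was listed at 0 on all arrays. The list's median was −0.17, with an adjusted p of 0.367 by camera and 0.614 with an estimated correlation. With median centring the list passed camera (adjusted p = 0.0198), but not with an estimated correlation there (adjusted p = 0.168). The median brightness of its members lay at percentile 79.2, so the same smaller rise of bright probes enters that pass. The mean of its members differed by −0.34 (exact permutation p = 0.0286, adjusted 0.143, both with the pairing of the arrays ignored). A part of that mean came from NdhN, at 0 on 7 of the 8 arrays; without members at 0 on any array the mean was −0.20.

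The plastid ribosomal proteins, the only list fixed beforehand that could be tested, did not pass the test. All 6 members missed the limma threshold, 0 passed when adjusted over the list alone and 0 had an unadjusted p under 0.05, and their median log2 difference was −0.09 (limma camera, p = 0.849; 0.852 with an estimated correlation). AT4G01310 and AT5G65220 had log2 differences of 0.43 ± 0.29 (SE) and −0.13 ± 0.14 (SE), the latter 0.35 in the deposited values. The mean of the members differed by −0.03 (exact permutation p = 0.771), and by 0.62 with median centring (exact permutation p = 0.0857). In the deposited values it differed by 1.46, where the exact permutation p of 0.0286 is the smallest possible. Both of these larger means include AT1G64510, at 0 on all arrays, whose deposited difference of 4.53 comes from the floor alone. The other members ran from 0.35 to 1.24 in the deposited values.

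The 9 cell division genes had a median of −0.21, with 7 of 9 negative, and none passed the limma threshold, while 1 had an unadjusted p under 0.05. Kinesin gene AT3G44050 had the smallest p among them, with a log2 difference of −0.57 ± 0.14 (SE; limma, adjusted p = 0.0605, and 0.0242 with the replicate block), and it was the 1 member lower when adjusted over the list alone. AT2G37420 had −0.14 ± 0.13 (SE). The deposited values of both turned direction, to 0.26 and 0.79 (limma, adjusted p = 0.151 and 0.0165). AT2G37420 thus passed as higher there, where most probes rose. Camera gave an adjusted p of 0.367, and 0.71 with an estimated correlation. Of the 10 organelle gene expression genes, 0 passed by limma and 1 had an unadjusted p under 0.05. CRR21, a factor of chloroplast RNA editing, had −0.34 ± 0.09 (SE, limma adjusted p = 0.0955), which turned to 0.55 in the deposited values. AT5G55580 had 0.32 ± 0.15 (SE), and it passed at 1.13 in the deposited values (limma, adjusted p = 0.0168). AT1G62150, at 0.38 ± 0.18 (SE; limma, adjusted p = 0.35), had an adjusted p of 0.0113 with the replicate block, and was singled out after its values were seen. Of the 10 developmental regulators, 0 passed over all probes by limma, 2 had an unadjusted p under 0.05 and 1, the Aux/IAA gene IAA31, was lower when adjusted over the list alone (−0.43 ± 0.10, SE; limma, adjusted p = 0.0621, and 0.0445 with the replicate block), though its deposited values were higher by 0.35. The MADS-box gene AGL54 had 0.60 ± 0.22 (SE; limma, adjusted p = 0.205), and it passed with the block of sets (0.0363) and, at 1.35, in the deposited values (0.00743). Camera gave adjusted p values of 0.504 and 0.701 for these lists, and 0.71 and 0.745 with an estimated correlation.

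The lists were also run through fry, which tests a list's own genes and does not compare them with other genes. For the photosynthetic apparatus the adjusted p was 0.143 for a shift in one direction and 0.014 for changes in either direction, or 0.0397 and 0.00401 without members at 0 on any array. For redox and defence these were 0.181 and 0.00433, or 0.0684 and 0.012. The other added lists had 0.51 to 0.892 and 0.154 to 0.197, and the plastid ribosomal proteins p values of 0.259 and 0.78.

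Replicates 1 and 2 of both light levels stood apart from replicates 3 and 4. The first principal component, with 53.0% of the variance, separated these sets, and the second, with 23.2%, separated the light levels. Computed within each set, the log2 differences between the light levels correlated with r = 0.585 across the 2600 probes above 0 on all arrays, which are not independent replicates. Replicates 1 and 2 alone gave 343 calls and replicates 3 and 4 alone 637, of which 102 and 151 were among the 235. AT3G52960 had log2 differences of 0.89 and 1.16 in the sets, CCS −0.99 and −0.91, and AT1G24040 −1.32 and −1.05. The sets lay further apart for AT1G07460 (0.75 in replicates 1 and 2, 2.0 in replicates 3 and 4), AT4G18540 (0.29 and 0.90) and AT1G13990 (−0.66 and −1.39). The difference between the light levels itself differed between the sets on 199 probes (interaction in limma), 12 of them among the 235.

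**Figure D3:**
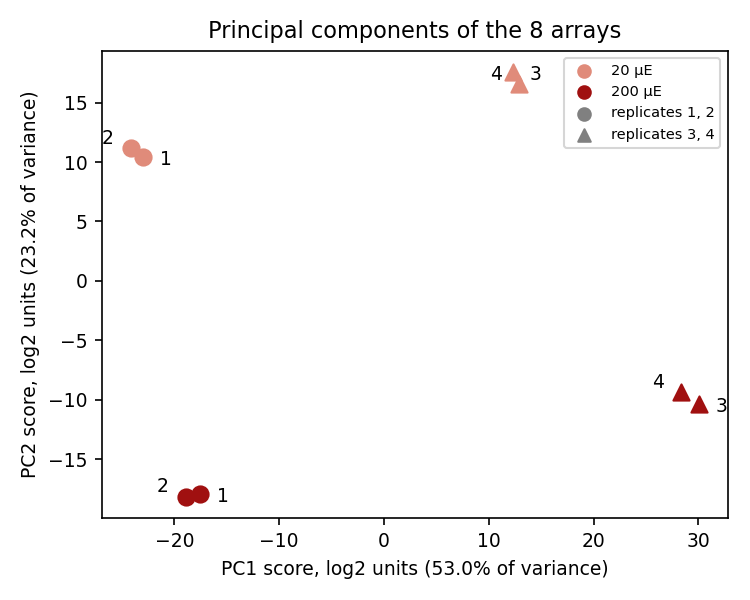
Scores of the 8 arrays on the first 2 principal components of the log2 normalized intensities of 2600 probes (axes in log2 units, with the percent of variance), colour giving the light level and the number the replicate. Replicates 1 and 2 lie apart from replicates 3 and 4 along the first axis (53.0%), and the light levels lie apart along the second (23.2%).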

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

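The test for an array far from the others of its group was fixed before the data were examined, and no explanation was tested for these values. Of 66 groups of 4 arrays examined, 4 held such an array, where chance gives about 1 in 20. The count of 4 is therefore near what chance alone gives. The test also takes the 4 arrays of a group as alike, while each group holds arrays of both sets.

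AT1G68660 was higher on the 200 µE array of replicate 2, at −0.98 on the log2 scale against a mean of −1.15 on the others, and the gap made up 0.905 of the group's range. AT1G34270 was lower on the 20 µE array of replicate 1, at −1.48 against −1.03, with a gap of 0.864 of the range. AT5G65220 was lower on the 200 µE array of replicate 3, at 0.05 against 0.58, with a gap of 0.841. LHB1B2 was lower on the 200 µE array of replicate 1, at 2.4 against 2.87, with a gap of 0.914.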

How the results depend on the processing

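The placements of the floor, the array set as a block, the single sets and the averaged sets were chosen after the data had been seen; the other settings were fixed before. The count of 235 became 927 with the deposited values (112 shared), 146 without the lowest 25% of probes, 156 without probes at 0 on any array, 619 with the replicate block, 94 with the plain unequal-variance test, 97 with a floor set per array after normalization, 746 with the array set as a block, 637 with replicates 3 and 4 alone and 6 with averaged sets. It stayed within 1.5 times with median centring (212, of which 135 were among the 235), cyclic loess (200, 183 of them shared), the pseudocount (244), trend and robust settings (224), a common floor after normalization (232, all among the 235) and replicates 1 and 2 alone (343). Without single arrays it ran from 140 to 174: 140 without 20 µE replicate 3 or 4, and 144, 148 and 152 without 200 µE replicates 2, 3 and 4. Fewer arrays were fitted there, and averaging leaves 2 against 2; the other causes were not tested. In simulated data, which left out the pairing of the arrays, the set block gave 28 false calls and the fit with no block 1. Of the 30 named genes, the deposited values turned 7: AT1G34270 (0.0227), FZL (0.54), AT2G37420 (0.79), AT5G65220 (0.35), CRR21 (0.55), AT3G44050 (0.26) and IAA31 (0.35). Median centring, which keeps the smaller rise of bright probes in the deposited values, turned AT4G39690 (−0.0634) and AT4G19900 (−0.75). Replicates 3 and 4 alone turned AT4G01310 (−0.0015) and AT5G55580 (−0.0088). Of the 10 rises, 9 were kept with the deposited values, where most probes rose, 1 with median centring and 4 under each filter. Of the 10 falls, these settings kept 1, 8 and all 10. The floor per array after normalization ended 8 rises and 3 falls, the plain unequal-variance test 5 and 5, and single left-out arrays 3 to 6 rises and 1 to 5 falls. Cyclic loess turned none and ended 3 calls, the replicate block ended 4 and added 3, the set block ended 0 and added 5, and averaged sets ended 20. The mean of the plastid ribosomal proteins went from −0.03 to 1.46 with the deposited values (exact permutation p = 0.0286, the smallest possible). It went to 0.62 with median centring, 0.0462 with cyclic loess and −0.67 with the floor per array after normalization. The shift of the whole array enters the 1.46. AT1G64510, at 0 on all arrays, takes a difference from the floor in the deposited values (4.53). It also takes one with median centring and with the floor per array after normalization. Medians turned with the deposited values for the plastid ribosomal proteins (0.95), photosynthetic apparatus (0.67) and cell division (0.85). With median centring those of the plastid ribosomal proteins (0.11) and cell division (0.0087) turned. Replicates 1 and 2 alone turned organelle gene expression (−0.0591). The medians with the deposited values and with median centring include members at 0 on all arrays, whose difference comes from the floor. For cell division this is AT4G14330, at 4.53 in the deposited values. The turn of the cell division median with median centring rests on that member's floor value. No list passed camera in any setting except the photosynthetic apparatus with median centring (median −0.17, adjusted p = 0.0198, and 0.168 with an estimated correlation), against 0.0585 to 0.612 for that list in the others, or up to 0.806 with an estimated correlation. The replicate block changed no list's call.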

Other observations

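The tests of the brightness classes and of the replicate numbers were chosen after the results they bear on had been seen; the split count was written before the counts were seen but after the array sets had been, and the test of the probe names before. NdhS, a subunit of the chloroplast NADH dehydrogenase-like complex, had a log2 difference of 0.53 ± 0.22 (SE; limma, adjusted p = 0.284, and 0.042 with the replicate block). AT5G58330, an NADP-malate dehydrogenase, had −0.59 ± 0.35 (SE; limma, adjusted p = 0.453, and 0.0453 with the replicate block). The deposited values of AT5G58330 were higher at 200 µE, by 0.33. Both genes were chosen after their values were seen.

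Of the 35 splits of the 8 arrays into 4 and 4, 2 gave as many calls as the light levels (235), the real one included, so chance is not excluded at a share under 0.05. The other was replicates 1 and 2 against replicates 3 and 4, with 988 calls, which points to a structure of the arrays, and the highest of the remaining splits gave 2. With the array set as a block 746 probes differed between the light levels, and with the replicate block 619. Among the 8 splits that part all 4 replicate numbers, only the real one gave as many, and the highest other gave 1; the others mix the light levels within each side.

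Replicates 1 and 2 stood apart from replicates 3 and 4 at both light levels. If only this set were shared, same-numbered arrays would deviate together no more than differently numbered arrays of a set, but their mean correlation of deviations was higher by 0.267, and higher by over 0.1 in all 4 numbers. A shared hybridisation or harvest for each number may add to the set, and no label tests it. With the arrays of each set averaged, 6 probes passed, so if the arrays of a set are repeats of 1 RNA the calls rest on fewer samples than 4 per level. No biological explanation of the sets was tested.

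The deposited values were higher at 200 µE for most probes. A single scale factor per array, as scaling to the brightest probes would give, predicts the same log2 difference at every brightness; the dimmest class exceeded the brightest by 0.547, which argues against it as the whole cause. A constant background added at 200 µE predicts equal linear differences, but the largest class median was 3.89 times the smallest. Both together predict linear differences on a straight line in the level at 20 µE, but the third class lay above the line through the dimmest and brightest by 0.115 (95% bootstrap interval over probes 0.09 to 0.135, and 0.0883 to 0.15 in the 4 same-numbered pairs of arrays). These predictions assume that bright and dim transcripts do not themselves change by different amounts, which was not tested. Beside such a change, neither a scale factor nor a background is excluded. A bent scanner response or more RNA of most transcripts under bright light could each remain, since each would follow the light level and was not tested.

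The platform's gene names could not be checked against the values. Over 52 pairs of probes listed with the same gene or genes, the log2 differences correlated with 0.338 across probes, above the 95th percentile of 10000 random pairings (0.218), and the mean levels with 0.227 (95th percentile 0.214). Only 1 of these pairs is listed with a single gene and 51 with several, so the test does not bear on the single-gene names used here, and whether those carry information on the probes stays open.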
